A study of Acipenser transmontanus with 8 samples.

How the data were processed

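The series holds 8 liver samples of white sturgeon, of which 4 have values in the deposited tables: control, TCDD, PCB 77 and BaP. The other 4 (β-naphthoflavone, selenomethionine and their controls) served, per the labels, to build the reference transcriptome and have no values. Per the labels, 16 fish aged 3 years were held at 12 °C in 400 L tanks, 1 tank per treatment, and RNA with an integrity number of at least 8 was kept. RNA from about 30 mg of each liver was pooled in equal amounts to 2 µg per treatment, from 3 control fish and 4 fish of each other treatment, and made into 1 library. Libraries were read as paired ends of 75 bases on a MiSeq or 100 bases on a HiSeq. Which sequencer read which library is not given in the sources used here, so sequencer and treatment cannot be separated.

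The submitters' processing notes name FastQC, edgeR and R 3.1.2, with no role or order; the aligner and the assembler are not given in the sources used here. Per the file headers, the authors gave for each treatment and contig a log2 fold change over the control, a log2 mean CPM (counts scaled to library size), a p-value and a false discovery rate. The deposited log2 fold change compares 1 treated library with the control library, and the deposited log2 mean CPM was the same in all 3 tables, so it averages the 4 libraries. The deposited p-value and adjusted p (FDR) come from the authors' test of 2 libraries, whose assumed dispersion is not stated. The other deposited files hold nucleotide sequences and no measurement: the reference transcriptome of 69312 contigs (73503479 bases, median 720) and, per treatment, the contigs with FDR under 0.05, which was tested on the files. The tables hold 18260 of these contigs (26.3%), with a median length of 1562 bases.

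The design assumed counts, while the files held fold changes. Counts were therefore recovered by solving, for each contig, for the 4 whole counts that give its deposited fold changes and mean CPM, with a prior count of 0.125 scaled to library size. Solutions whole within 0.001 were found for 18260 of 18260 contigs; the largest distance from a whole count was 0.000157, and the smallest of any second-best solution was 0.000764. The library sizes solved from the tables, relative to control, were 0.997, 1.02 and 0.924, and they differed by at most 8.66e-12 from those given by TMM scaling of the solved counts. An exact negative binomial test of the solved counts at an assumed biological coefficient of variation of 0.2 gave p-values within 1% of the deposited ones for 18259, 18260 and 18260 contigs in TCDD, PCB 77 and BaP. Library totals were 11871399 (control), 12230532 (TCDD), 11906381 (PCB 77) and 10813395 (BaP), with median counts per contig of 126, 124, 129 and 117, and the 10 most abundant contigs took 19.9%, 19.8%, 18.7% and 23.2%. The floor of 3 counts was 0.253, 0.253, 0.248 and 0.273 CPM. Every contig in the tables had at least 57 counts in its highest library, so the tables were already filtered on abundance.

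Libraries were scaled by trimmed mean of M values (TMM), recomputed in numpy, with factors from 0.968 in TCDD to 1.02 in PCB 77. The comparisons were each treatment against control and each pair of treatments. A contig passed when its log2 fold change with a prior count of 2 was at least 2 in size, its 95% Clopper-Pearson interval of the count ratio excluded 1 and it had at least 1 CPM in either library. No p-value was computed for a condition, since each had 1 library. Folds printed are ratios of scaled counts without a prior count, and log2 values carry it. Correlations and covariances were taken across contigs and set beside 100 simulations of unchanged groups that share 1 control, with counting error alone and with an assumed biological coefficient of variation of 0.2. Lists of the observed sizes were also taken by rank from these simulations, a comparison added after the data were seen, since few or no simulated contigs passed the size rule.

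The comparisons, the size rule, the gene lists, the rule for named contigs and most alternatives were chosen before the data were examined. The files pair no gene names with contigs, so lists were filled by protein signature (PROSITE-style patterns) in the longest open reading frame of at least 100 codons, which 14061 contigs had. Reversed proteins, searched the same way, gave the number of matches by chance: 9 against 19 for serpins, 11 against 35 for the immunoglobulin and MHC fold, 7 against 21 for aldehyde dehydrogenase, 5 against 39 for ABC transporters, 3 against 4 for tubulin and for GAPDH, 2 against 3 for aldo-keto reductase, and 1 each for fatty acid-binding proteins, lipases and cathepsins. The other planned signatures had 0. Of the planned lists 33 had a signature; 4 were defined by name alone (other AHR battery genes, glutathione S-transferases with sulfotransferases, erythrocyte and exocrine pancreas markers) and were not run. List intervals are those of the median over contigs for lists of 6 or more. Median percentiles come from 10000 random lists matched in 20 bins of mean expression.

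Named contigs were both contigs with the CYP1 signature, from each other list the passing contig with the largest mean change over the treatments, and the 2 highest and 2 lowest of the contigs with no fixed signature that passed in all 3 treatments. After the values were seen, 9 more signatures were added (a wider CYP1 heme peptide, the AHR and AHR repressor basic region, 2 sulfotransferase motifs, the ALAS1 leader, the albumin domain, 2 carboxypeptidase zinc sites and colipase). An alpha-amylase peptide and a phospholipase A2 pattern were also tried then and dropped, since the former matched no contig and the latter matched more reversed than forward proteins. Contigs named through added signatures or through similarity were chosen after their values were seen. Near-identical contigs were joined with BLAST+ at 95% identity or more over at least 50% of the shorter contig and at least 100 bases. Protein relatives of the CYP1 contigs were taken at 40% identity over at least 100 residues, and the group of CYP1A-type contigs at 95% nucleotide identity over at least 200 bases.

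The recovery and the size rule were tested on simulated data of 18260 contigs. Counts were recovered for 18260 contigs, and 0 of 18060 unchanged contigs passed. The simulated counts had counting error alone, so this gives no rate of false calls between pools of fish. Of 50 contigs changed 2-fold 0 passed; of 50 changed 4-fold 19, 29 and 25 passed in TCDD, PCB 77 and BaP; and of 50 changed 8-fold or 16-fold 50 passed. Alternatives were total-count and median-of-ratios scaling, no low-count filter and one of 5 CPM, a 2-fold threshold, a prior count of 0.5 and the mean of a list in place of its median. After the data were seen, summing near-identical contigs, leaving out the contigs of the digestive profile and other assumed values behind the deposited p-values were added. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88, matplotlib 3.10.9 and BLAST+ 2.17.0.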

Results

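Liver RNA was sequenced from juvenile white sturgeon (Acipenser transmontanus), a large freshwater fish, 3 days after an injection of corn oil alone or of 1 of 3 agonists of the aryl hydrocarbon receptor (AHR). The AHR is a ligand-activated transcription factor that switches on CYP1 enzymes. The agonists were TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin) at 5 µg/kg, the coplanar biphenyl PCB 77 at 5 mg/kg and the polycyclic hydrocarbon benzo[a]pyrene (BaP) at 30 mg/kg. Each treatment was 1 library, pooled from 4 fish, and the control library was pooled from 3 fish. The counts recovered from the deposited tables came to 11871399 in the control library, 12230532 in TCDD, 11906381 in PCB 77 and 10813395 in BaP, over 18260 contigs. Contigs carried no gene names, so they are named here by the final number of their identifier and by the protein signature of their reading frame.

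There were no replicates. Intervals are 95% exact binomial (Clopper-Pearson) intervals of count ratios, and these intervals and the floor of 3 counts cover counting error only. Each comparison therefore compares 2 libraries and not 2 conditions. Each treatment also had its own tank, so tank and treatment cannot be told apart. A contig was called higher or lower when its log2 fold change was at least 2 in size, its interval excluded 1 and it reached 1 CPM, the count scaled to library size, in either library.

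The comparison of TCDD with control asked which liver transcripts differed 3 days after the dioxin. CYP1 monooxygenases, which oxidise planar aromatic compounds, were among the contigs that rose most. Contig 8635, with the heme peptide of the CYP1A type, rose from 265 to 3893 CPM, which was 14.7-fold (14.2 to 15.3); summed over the 7 contigs of the CYP1A type the rise was 16.3-fold (15.8 to 16.7). Contig 24251, with a heme peptide of the CYP1B or CYP1C type, rose from 5 to 425 counts, 85.2-fold (36.2 to 264). Contig 16096 had a CYP1-like heme peptide outside the fixed CYP1 pattern and 57.7% protein identity to contig 24251 over 503 residues (59.0% over 481 in the reverse search), and it rose from 12 to 2193 counts, 183-fold (105 to 355). Of the contigs with no fixed signature found, those that rose most in all 3 treatments were contig 8599, 222-fold (116 to 485), and contig 7350, 233-fold (90.8 to 858); the reading frame of contig 8599, of 54 residues, was too short to be searched.

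Both CYP1 contigs rose in TCDD, and of the 35 contigs with a cytochrome P450 signature 4 rose, 1 fell and 30 did neither. The median of these 35 was 0.17 on the log2 scale (percentile 87.5 of random lists). Of 4 contigs with the signature of phosphoenolpyruvate carboxykinase (PEPCK), which starts glucose synthesis from oxaloacetate, contig 7351 rose 8.15-fold (6.64 to 10.1), from 104 to 845 counts. An aldehyde dehydrogenase (contig 3365, 1 of 21) rose 4.19-fold (3.92 to 4.48) and an ABC transporter (contig 22283, 1 of 39) rose 4.44-fold (3.33 to 5.99). In PCB 77 and BaP, where neither passed, contig 3365 was 3.04-fold and 1.65-fold over control and contig 22283 was 2.11-fold and 1.34-fold. One of 4 contigs with the signature of fatty acid-binding proteins, which carry lipids inside cells, fell: contig 46342 went from 794 to 7 counts, 113-fold lower. Contig 26270, 1 of 32 nuclear hormone receptors, fell 6.08-fold, from 128 to 21 counts. In PCB 77 it was 3.53-fold lower, which did not pass. Of the lists, 1 of 19 serpins, 1 of 13 fibrinogen-domain contigs and 1 of 29 trypsin-type proteases (one of the digestive-enzyme contigs described with BaP) also rose, and 2 of 35 contigs with the immunoglobulin and MHC fold fell. Among contigs outside the fixed signatures, contig 49313 went from 189 counts to 0, at least 62.8-fold lower against the floor of 3 counts in the TCDD library, and contig 37683 fell 41.4-fold, from 332 to 8 counts.

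In all, 218 contigs were higher and 170 lower in TCDD, of 18247 compared, and 86.5% of contigs differed by less than 2-fold. Many of these contigs have near-identical partners in the assembly, and with the counts of near-identical contigs summed 128 units were higher and 119 lower.

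**Figure D1:**
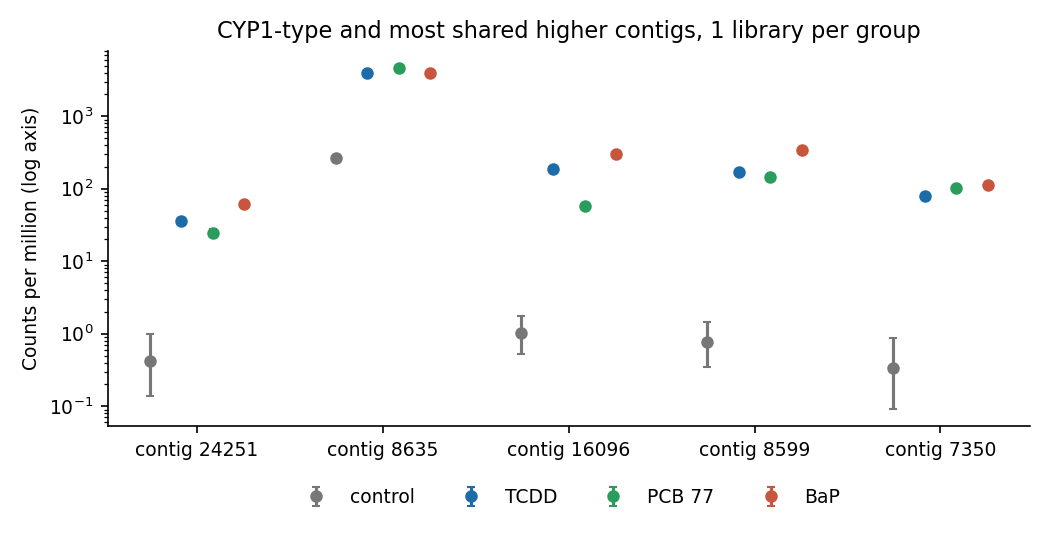
CPM (log axis) of 5 contigs in the control, TCDD, PCB 77 and BaP libraries, with 1 point per library and bars for the 95% interval of the count. Contig 8635 went from 265 CPM in control to between 3893 and 4620 CPM in the treated libraries, and contig 16096 from 1.01 CPM to between 58.2 and 305 CPM.

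PCB 77 against control asked the same of a coplanar polychlorinated biphenyl, which shares with TCDD the chlorinated aromatic rings but not the dioxin bridge. CYP1 contigs again rose: contig 8635 reached 4620 CPM, 17.5-fold (16.8 to 18.1) over control. Contig 24251 rose 58.6-fold (24.8 to 182) and contig 16096 rose 57.6-fold (32.7 to 112). The PEPCK contig 7351 rose 9.03-fold (7.37 to 11.2), to 959 counts. In the other direction, contig 46342 of the fatty acid-binding proteins went from 794 to 5 counts, 162-fold lower.

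Of the 35 P450 contigs, the 3 named above rose in PCB 77 and none fell, and the list median was 0.59, above 100% of random lists after rounding. A serpin, of the family of plasma protease inhibitors made in liver, rose 5.94-fold (5.01 to 7.09) at contig 13845. This contig was 3.78-fold over control in TCDD, which did not pass. Of the 19 serpin contigs 2 rose and 1 fell in PCB 77. Of the 35 contigs with the immunoglobulin and MHC fold, contig 14033 rose 7.56-fold (4.32 to 14.3). It was 2.72-fold over control in TCDD and 4.33-fold in BaP, and passed in neither. Thioredoxin-fold chaperones, most of which help secreted proteins form disulfide bonds, lay lower as a group: 2 of 15 fell, 7 were at least 2-fold lower, 1 at least 2-fold higher, and the median was −0.99 (−1.53 to −0.20). Contig 14079 of this list fell 5.38-fold, from 7147 to 1356 counts. In TCDD it was 2.93-fold lower, which did not pass. Trypsin-type proteases (4 of 29) and a carboxylesterase (1 of 3) fell as well, among them contig 57250 at 5.89-fold and contig 7436 at 5.66-fold lower. Contig 7436 and 3 of these 4 trypsin-type contigs belong to a set of digestive-enzyme contigs described with BaP; the other, contig_14421, named after its values were seen, had 1234, 615, 255 and 359 counts in control, TCDD, PCB 77 and BaP. One fibrinogen-domain contig rose and 1 fell. Contigs 8599 and 7350 rose 191-fold (100.2 to 418) and 305-fold (119 to 1123). Contig 49313, at 1 count, had a ratio to control of 0.00518 (0.000131 to 0.0292), and contig 37683, at 3 counts, one of 0.00885 (0.00182 to 0.0261).

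PCB 77 gave 203 higher and 196 lower contigs of 18246 compared, and 85.3% of contigs differed by less than 2-fold. With near-identical contigs summed, 122 units were higher and 128 lower.

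BaP against control addressed an unchlorinated polycyclic hydrocarbon, which CYP1 enzymes themselves oxidise. Contig 8635 rose 15.01-fold (14.5 to 15.6) to 3971 CPM, contig 24251 rose 146-fold (62.1 to 450) and contig 16096 rose 302-fold (173 to 585). Some contigs with a signature found in digestive enzymes fell. They are called digestive-enzyme contigs here by signature alone, since no contig was matched to a pancreatic protein. Of 29 trypsin-type proteases 6 passed as lower and 23 did not pass, with a list median of −0.22 (percentile 5.33), and 1 of 3 carboxylesterases passed as lower. Contig 57250 went from 2158 to 23 counts (86.7-fold lower) and the carboxylesterase contig 7436 from 4716 to 43 counts (101-fold lower). Fibrinogen-domain contigs, the family of the clotting protein made in liver, included 3 of 13 that fell; 7 were at least 2-fold lower and 1 at least 2-fold higher, and the median was −1.35 with an interval of −2.10 to 0.42 (percentile 0). Contig 522 of this list fell 11.4-fold, from 2414 to 195 counts.

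Of the 35 P450 contigs 5 rose in BaP and none fell, with a median of 0.42 (percentile 99.99) and an interval of −0.01 to 0.78. UDP-glucuronosyltransferases conjugate drugs and hormones for excretion, and contig 466, 1 of 8, rose 4.27-fold (3.87 to 4.71). It was also 3.17-fold over control in TCDD and 2.33-fold in PCB 77, which did not pass. The glucose-6-phosphate dehydrogenase contig 39282, from the pathway that supplies NADPH, rose 4.67-fold (2.68 to 8.61) at 16 and 69 counts. The serpin contig 13845 rose 10.5-fold (8.87 to 12.4), and 2 of the 19 serpins rose. Thioredoxin-fold contig 14079 fell 4.06-fold and was the 1 of 15 that fell. Of this list 7 were at least 2-fold lower and 1 at least 2-fold higher, with a median of −0.89 (−1.18 to −0.10). Fatty acid-binding contig 46342 fell 15.6-fold and the nuclear receptor contig 26270 fell 5.92-fold. The PEPCK contig 7351 had 59 counts against 104 in control, a log2 fold change of −0.69 that did not pass. Contigs 8599 and 7350 rose 451-fold (237 to 988) and 330-fold (129 to 1213), and contigs 49313 and 37683 fell 43.7-fold and 17.05-fold.

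The digestive-enzyme contigs that fell did not keep 1 level in the other libraries. Counting carboxypeptidase signatures, which were chosen after the values were seen, 11 contigs with a digestive-enzyme signature fell in BaP: 6 trypsin-type, 4 carboxypeptidase and 1 carboxylesterase. The carboxypeptidase contigs were 2 of 8 with the first zinc site and 3 of 14 with the second (3 matches by chance), 1 of them with both, and the medians of these lists in BaP were −0.09 and −0.01, at percentiles 29.8 and 49.8. The set was thus picked for its fall in BaP. Their summed level was 1658 CPM in control, 4023 in TCDD, 367 in PCB 77 and 20.9 in BaP. Their log2 fold changes ran from 0.81 to 2.23 in TCDD, from −2.55 to −1.32 in PCB 77 and from −8.43 to −4.90 in BaP. The 1 contig matching a colipase signature, a cofactor of pancreatic lipase also chosen then, had −0.26, 0.57 and −0.10 in TCDD, PCB 77 and BaP; its 9 matched residues were of 2 kinds, so the match decides nothing.

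**Figure D2:**
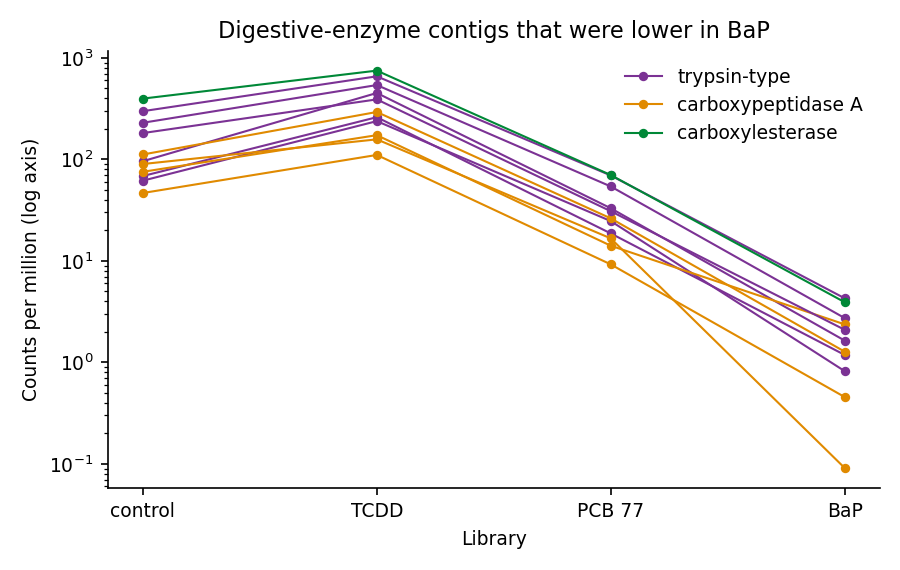
CPM (log axis) of the 11 contigs with a digestive-enzyme signature that were lower in BaP, in the control, TCDD, PCB 77 and BaP libraries. Each line joins the points of 1 contig and has no meaning between libraries; the summed level went from 1658 CPM in control to 4023, 367 and 20.9 CPM.

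BaP gave 291 higher and 252 lower contigs of 18253 compared, and 84.8% differed by less than 2-fold. Without the 28 contigs whose 3 log2 fold changes lay within 1 of the medians of the lower trypsin-type contigs, the contigs lower in BaP numbered 224 and those lower in PCB 77 numbered 175, and with near-identical contigs summed 198 units were higher and 162 lower.

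The study's question was how alike the liver's responses to the 3 agonists were, at doses the submitters selected for equal potency at the AHR. CYP1 contigs, the unnamed contigs 8599 and 7350 and others, 82 in all, were higher in all 3 treatments, and 24 contigs, among them the fatty acid-binding contig 46342, were lower in all 3. TCDD and PCB 77 shared 106 higher and 54 lower contigs, TCDD and BaP 127 and 54, and PCB 77 and BaP 128 and 70. Another 236 contigs were higher and 334 lower in exactly 1 treatment. Of the contigs higher in TCDD, 155 of 218 (71.1%) were at least 2-fold higher in both other treatments, and of those lower in BaP, 98 of 252 (38.9%) were at least 2-fold lower in both.

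The 3 comparisons share 1 control library, which cannot be split, so part of the overlap may come from that library. Lists of the same sizes, taken by rank from groups simulated as unchanged against 1 control with counting error alone, shared on average 29.4 higher contigs (17 to 41 over 100 simulations) and 7.59 lower (2 to 13) over all 3 treatments, against the 82 and 24 observed. For TCDD and PCB 77, TCDD and BaP, and PCB 77 and BaP the averages were 56.6, 68.0 and 66.1 higher and 24.8, 28.8 and 31.7 lower. With an assumed biological coefficient of variation of 0.2, 23.35 higher and 2.97 lower contigs were shared by all 3. In those simulations 11.3% (6.42% to 18.3%) of the contigs ranked as higher in TCDD were at least 2-fold higher in both others, and 1.90% (0% to 3.97%) of those ranked as lower in BaP were at least 2-fold lower in both. These ranked contigs changed less than the observed ones, since on average 0.41 passed as higher in TCDD and 0.39 as lower in BaP. A 2-fold mark was thus harder to reach, so these percentages cannot be set against the observed 71.1% and 38.9% as a measure of sharing. Agreement in sign differed by set. Of the contigs higher in TCDD, 90.4% had the same sign in both others, against 92.0% (87.6% to 97.2%) in the same simulations. Of those lower in BaP it was 69.4%, below every such simulation (mean 79.4%, 73.4% to 86.5%). Of those lower in PCB 77 it was 73.0%, also below every one (mean 80.8%, 74.5% to 86.7%). The ranges with counting error alone, 69.4% to 81.0% and 70.9% to 84.7%, reached these values. All 28 contigs that followed the lower trypsin-type contigs were in the former set, and 21 were in the latter. They were above control in TCDD, so they lowered both shares, and shares without them were not computed. Of those lower in TCDD it was 87.1%, against 81.5% (72.9% to 88.2%). Of those higher in BaP it was 93.8%, against 91.1% (84.5% to 95.9%), and above the 80.8% to 90.7% with counting error alone. Across the 18260 contigs, which are not independent replicates, log2 fold changes of TCDD and PCB 77 correlated with Pearson's r = 0.647 and Spearman's rho = 0.587, TCDD and BaP with 0.597 and 0.609, and PCB 77 and BaP with 0.664 and 0.637. Groups simulated as unchanged against 1 control gave a mean r between 0.489 and 0.503, since the shared control alone correlates the differences. The covariance, which grows with the size of the shared part, was 0.386, 0.396 and 0.452 for the 3 pairs, against 0.0184, 0.0184 and 0.0183 simulated with counting error alone and 0.102 for each with an assumed biological coefficient of variation of 0.2. By the size rule, no contig passed in any treatment in the 100 simulations with counting error alone, so none could be shared by all 3. With an assumed coefficient of 0.2, a mean of 0.41 contigs passed as higher in TCDD, and 0.05 higher and 0 lower were shared by all 3. At these settings the size rule thus gives no simulated scale for the observed overlap. No simulation was run at a larger coefficient, such as the 0.452 of the control pool that alone would give the covariance of TCDD and PCB 77. With near-identical contigs summed, 46 higher and 14 lower units were shared by all 3.

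**Figure D3:**
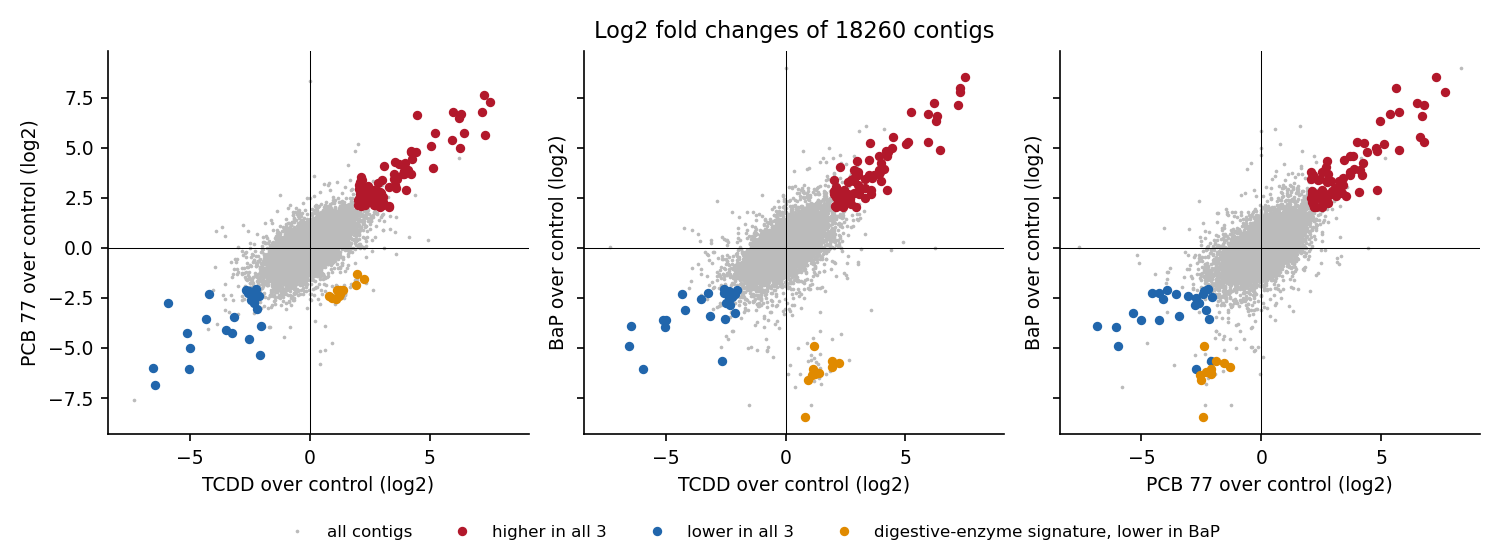
Log2 fold changes over the shared control of 18260 contigs, each pair of treatments in its own panel, with contigs higher or lower in all 3 treatments and the digestive-enzyme contigs lower in BaP coloured. The 82 contigs higher and the 24 lower in all 3 lie along the diagonal, and the 11 digestive-enzyme contigs lie off it in every panel, with medians of 1.23 in TCDD, −2.10 in PCB 77 and −6.22 in BaP.

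Direct comparisons of the treated libraries do not use the control. The CYP1A-type contig 8635 differed little between them: PCB 77 was 1.19-fold (1.17 to 1.20) over TCDD and 1.16-fold (1.15 to 1.18) over BaP, and BaP was 1.02-fold (1.01 to 1.03) over TCDD. The other CYP1-type contigs differed more, and in contig 16096 BaP was 5.25-fold (4.84 to 5.70) over PCB 77, which passed, and 1.65-fold (1.56 to 1.74) over TCDD, which did not. In contig 24251, BaP was 2.49-fold (2.17 to 2.86) over PCB 77, which did not pass. PEPCK contig 7351 was higher in TCDD and in PCB 77 than in BaP, by 13.3-fold (10.2 to 17.6) and 14.7-fold (11.3 to 19.5), and it was 1.11-fold (1.01 to 1.22) higher in PCB 77 than in TCDD, which did not pass. Fatty acid-binding contig 46342 was higher in BaP than in TCDD, 7.25-fold (3.25 to 19.0), and than in PCB 77, 10.4-fold (4.15 to 33.4). The fibrinogen-domain contig 522 was 6.05-fold (5.20 to 7.07) higher in TCDD and 4.38-fold (3.75 to 5.14) higher in PCB 77 than in BaP. Carboxylesterase contig 7436 and trypsin-type contig 57250 were higher in TCDD than in PCB 77, by 10.7-fold (9.96 to 11.5) and 12.6-fold (11.4 to 14.1), and higher in PCB 77 than in BaP, by 17.9-fold (13.2 to 24.9) and 14.7-fold (9.67 to 23.5). In contig 37683 BaP was 6.63-fold (1.93 to 35.1) over PCB 77, at 18 and 3 counts, and passed.

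Between TCDD and PCB 77, 108 contigs were higher and 94 lower in TCDD. Against BaP, 162 were higher and 115 lower in TCDD, and 171 were higher and 132 lower in PCB 77. The share of contigs differing by less than 2-fold was 90.2% between TCDD and PCB 77, 90.4% between TCDD and BaP and 90.2% between PCB 77 and BaP. Mass doses differed between the agonists, and near-identical contigs summed gave 69 higher and 60 lower units for TCDD against PCB 77, 108 and 72 for TCDD against BaP and 114 and 80 for PCB 77 against BaP.

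The medians of several gene lists, few of whose contigs passed, are given over control, each with its percentile among the medians of 10000 random lists matched on expression, as a description of these libraries. Both contigs with the signature of the HSP90 chaperones were at least 2-fold lower in all 3 treatments, with medians of −1.52 in TCDD, −1.72 in PCB 77 and −1.38 in BaP, at percentiles 0.18, 0.16 and 1.82. Neither was matched to a reference protein, so which HSP90 they encode is not known. Thioredoxin-fold contigs had a TCDD median of −0.47 with an interval of −1.24 to 0.04 (percentile 0.21), with 5 of 15 at least 2-fold lower, and percentiles of 0 in PCB 77 and BaP. Nuclear hormone receptors had medians of 0.20, 0.45 and 0.36 in TCDD, PCB 77 and BaP, at percentiles 93.07, 99.95 and 99.81, with 1, 0 and 1 of 32 falling. UDP-glucuronosyltransferases had medians of 0.37, 0.43 and 0.30 (percentiles 93.57, 95.06 and 93.57), ABC transporters 0.08, 0.19 and 0.25 (68.2, 93.9 and 98.6) and aldehyde dehydrogenases 0.07, 0.40 and 0.02 (55.7, 99.2 and 60.7). Fibrinogen-domain contigs had medians of −0.44 and −0.49 in TCDD and PCB 77, at percentiles 0.745 and 0.555, with intervals of −0.90 to 0.75 and −1.38 to 1.09. Contigs with the immunoglobulin and MHC fold, a list planned for immune cells, had medians of 0.34, 0.38 and 0.41, at percentiles 99.7, 99.82 and 99.97. Of its 35 matches 11 are expected by chance, and no contig was assigned to a cell type, so the list does not measure leukocytes.

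**Figure D4:**
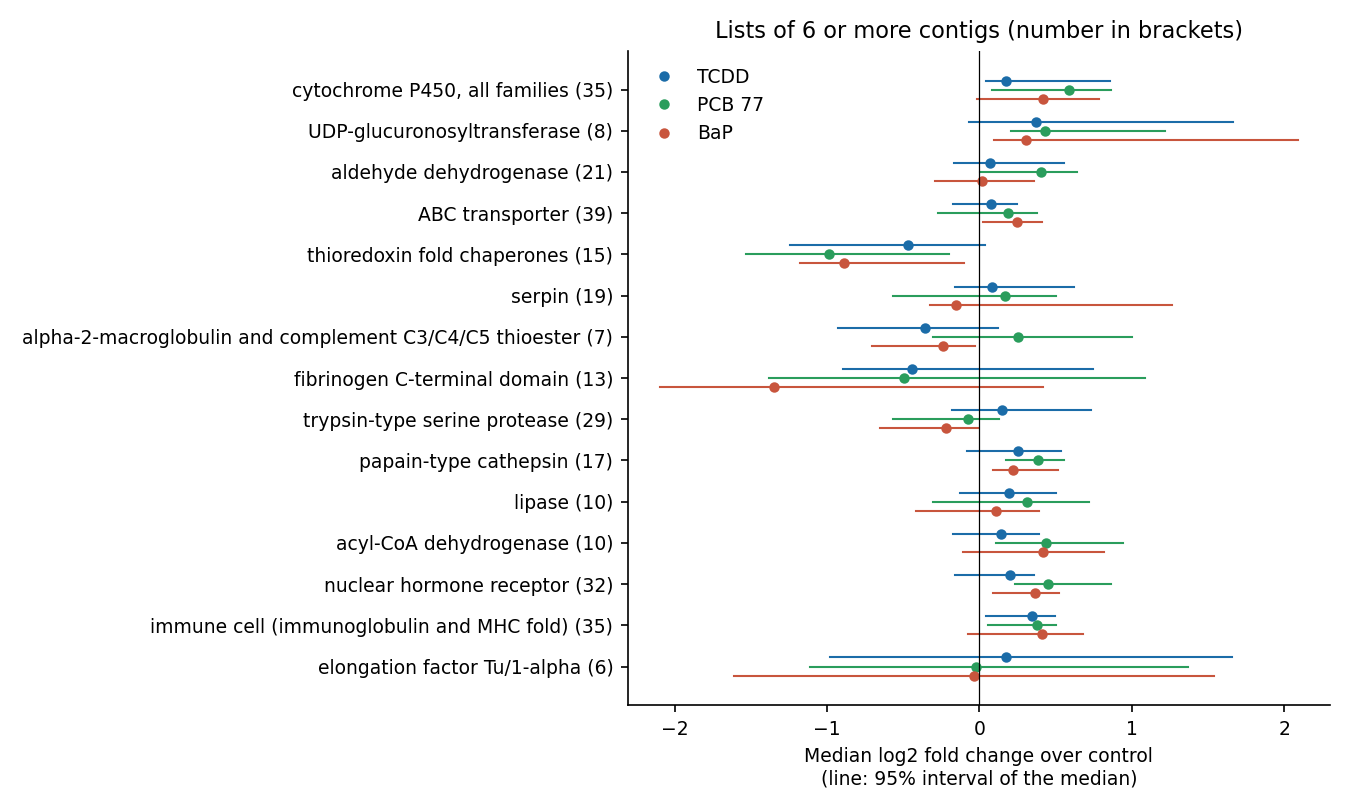
Median log2 fold change over control of each list with 6 or more contigs, in TCDD, PCB 77 and BaP, with lines for the 95% interval of the median over the list's contigs. Thioredoxin-fold chaperones lie at −0.47, −0.99 and −0.89 and P450 contigs at 0.17, 0.59 and 0.42.

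Other lists held no contig that passed in any treatment, and their medians are given for TCDD, PCB 77 and BaP in that order. Heat shock protein HSP70 (4 contigs) had 0.65, 0.41 and 0.56, catalase (3) 0.17, 0.05 and 0.21, Cu/Zn superoxide dismutase (1) −0.22, −0.26 and −0.11, ferritin (2) 0.17, −0.13 and −0.02 and transferrin (4) −0.14, 0.23 and 0.27. Thioester plasma proteins (7) had −0.35, 0.26 and −0.24, papain-type cathepsins (17) 0.26, 0.38 and 0.22, lipases (10) 0.19, 0.31 and 0.11, and acyl-CoA dehydrogenases (10) 0.14, 0.43 and 0.42. Aldo-keto reductases (3) had −0.20, −0.26 and −0.21, enolase (1) −0.24, −0.87 and −0.50, tubulins (4) 0.33, 0.08 and 0.43, elongation factor Tu/1-alpha (6) 0.17, −0.02 and −0.04, and GAPDH (4) 0.31, −0.02 and −0.22. With total-count scaling the sign flipped for ferritin in BaP and for elongation factor Tu/1-alpha and GAPDH in PCB 77.

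Among lists with passing contigs, the serpin medians were 0.09, 0.17 and −0.15, the trypsin-type medians 0.15, −0.08 and −0.22, the carboxylesterase medians −0.51, −0.81 and −0.68, the PEPCK medians 0.48, 1.08 and −0.09 and the fatty acid-binding medians 0.10, −0.20 and 0.29. The CYP1 medians were 4.90, 4.76 and 5.30. The glucose-6-phosphate dehydrogenase contig had 1.88, 1.78 and 2.09. Mean and median differed in sign for fatty acid-binding proteins in TCDD (mean −1.26) and BaP (mean −0.33), HSP70 in PCB 77 (mean −0.08), serpins in BaP (mean 0.32), aldehyde dehydrogenases in BaP (mean −0.0022) and aldo-keto reductases in BaP (mean 0.0080). In planned lists whose percentiles are not given above, those under 2 or over 97 were 100 for CYP1 contigs in each treatment, 97.77 for HSP70 in TCDD, 97.26 and 98.3 for acyl-CoA dehydrogenases in PCB 77 and BaP, and 97.975, 97.17 and 97.975 for glucose-6-phosphate dehydrogenase in TCDD, PCB 77 and BaP. In PCB 77 they were 97.49 for cathepsins, 99.86 for PEPCK and 1.545 for carboxylesterases. No contig matched the metallothionein, actin or zona pellucida signatures.

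The authors' deposited lists held 1094 contigs for TCDD (554 higher, 540 lower), 1272 for PCB 77 (666 and 606) and 1405 for BaP (745 and 660). Each list was the set of contigs whose deposited adjusted p was under 0.05, and the smallest change in it was 1.25, 1.23 and 1.21 on the log2 scale. Every contig that passed the size rule, CYP1 contigs included, was in the list of its treatment. The lists shared 185 higher and 109 lower contigs over all 3 treatments. Lists of these sizes taken by rank of the same test's p from unchanged groups that share 1 control held 92.5 (72 to 110) and 48.2 (33 to 64) in common with counting error alone, and 76.4 and 29.1 with an assumed biological coefficient of variation of 0.2. TCDD and PCB 77 shared 268 higher and 200 lower contigs, TCDD and BaP 272 and 200, and PCB 77 and BaP 315 and 253. For these pairs the unchanged groups with counting error alone shared on average 180.7, 186.9 and 213.3 higher and 125.7, 126.8 and 138.6 lower. The deposited p-values were those of a test at an assumed biological coefficient of variation of 0.2; at 0.1, 0.3 and 0.4 the TCDD list would hold 4809, 206 and 47 contigs.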

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

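The tests of explanations in this part were chosen after the results were seen. Some contigs moved in opposite directions between treatments: each passed as higher in one treatment and as lower in another, against the same control. The difference between treatments was not tested for a condition, since each had 1 library. There was 1 contig higher in TCDD and lower in PCB 77, there were 4 higher in TCDD and lower in BaP, 1 lower in TCDD and higher in BaP, 1 higher in PCB 77 and lower in BaP, and 1 lower in PCB 77 and higher in BaP. They are named here after their values were seen. Counts in control, TCDD, PCB 77 and BaP were 149, 935, 34 and 1 for contig_7705, 53, 655, 44 and 4 for contig_6035, and 38, 198, 10 and 0 for contig_33586. They were 243, 32, 39 and 1132 for contig_31585 and 623, 1942, 2606 and 130 for contig_7461. The trypsin-type contig_1930 had 1140, 5343, 400 and 18 counts, with log2 fold changes of 2.23, −1.54 and −5.73 in TCDD, PCB 77 and BaP, and it belongs to the digestive-enzyme contigs.

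Those 11 contigs with a digestive-enzyme signature fell in BaP, and their levels also differed between the other libraries. Scaling between libraries is argued against, since a scaling factor moves all contigs of a library alike and 84.8% differed by less than 2-fold in BaP. The 2 other scalings moved the median BaP log2 fold change of the 11 contigs by at most 0.0152, against a median of −6.22. That test adds little, since total-count scaling moved the median BaP contig by only 0.0208. Unequal amounts of pancreatic RNA in the liver pools stay open: 1 source of fixed composition would keep its transcripts in 1 ratio, and the SD of their log2 fold changes was 0.457 in TCDD, 0.399 in PCB 77 and 0.862 in BaP, against 1.503, 1.303 and 1.328 in the 241 other contigs lower in BaP. The largest SD, in BaP, included contig 9284 at −8.43 with 1 count, under the floor of 3 counts. In TCDD the log2 fold changes ran from 0.81 to 2.23, so the contigs did not keep 1 exact ratio there either. The composition of such RNA in each pool is unknown, with 1 pool per treatment. The colipase match, at −0.26, 0.57 and −0.10 in TCDD, PCB 77 and BaP, lay outside this profile. That match decides nothing, since its 9 residues were of only 2 kinds, and the planned pancreas list, defined by name alone, could not be run. An effect of the treatments on the digestive enzymes, with a difference of 7.46 between the median log2 fold changes of TCDD and BaP, cannot be told apart from a difference between pools, because there was 1 pool per treatment.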

How the results depend on the processing

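Summing near-identical contigs, leaving out the digestive profile and the assumed variation behind the deposited p-values were chosen after the data were seen. No paired analysis was possible because each treatment had 1 library. Counts summed over contigs that share a name were planned and not run, since the files pair no names with contigs, and pseudocounts for normalized units did not apply, since counts were recovered. Under both other scalings, both filters and the prior count of 0.5, each where planned, the counts of contigs stayed within 1.5 times those reported: 190 to 231 higher and 167 to 191 lower in TCDD, 180 to 224 and 190 to 218 in PCB 77, 281 to 316 and 241 to 270 in BaP, and 62 to 94 and 24 to 29 in all 3 treatments. Under these settings the correlations stayed within their resampling intervals. The filter of 5 CPM could not move them, since every contig had at least 57 counts in its highest library and none was removed. For the same reason, leaving out the low-count filter moved counts of contigs by at most 1. A 2-fold threshold admits more contigs by construction: 1195 higher and 1264 lower in TCDD, 1445 and 1241 in PCB 77, 1382 and 1383 in BaP, 437 and 323 in all 3, 766 and 1010 for TCDD against PCB 77, 833 and 914 for TCDD against BaP, and 958 and 823 for PCB 77 against BaP. With near-identical contigs summed, fewer units were tested: 128 were higher in TCDD, 122 higher and 128 lower in PCB 77, 162 lower in BaP, and 46 higher and 14 lower in all 3. Then 69 were higher and 60 lower in TCDD than in PCB 77, 108 higher and 72 lower in TCDD than in BaP and 114 higher and 80 lower in PCB 77 than in BaP. Covariances of TCDD with PCB 77, TCDD with BaP and PCB 77 with BaP were 0.331, 0.338 and 0.392 with near-identical contigs summed and 0.418, 0.426 and 0.489 with a prior count of 0.5; the cause was not tested. Without the contigs of the digestive profile, r for TCDD and BaP was 0.642. These contigs were chosen for fold changes that differ between TCDD and BaP, so the rise from 0.597 decides nothing. The BaP mean was 0.91 for P450 contigs and −1.30 for trypsin-type contigs, in place of medians of 0.42 and −0.22. These means take in extreme contigs, up to 8.01 for P450 and down to −6.33 for trypsin-type contigs. Cu/Zn superoxide dismutase in TCDD was −0.27 with total-count scaling, in place of −0.22, and that scaling moved all contigs in TCDD by a median of −0.046. At assumed biological coefficients of variation of 0.1, 0.3 and 0.4, the authors' test would list 4809, 206 and 47 contigs in TCDD, 5325, 206 and 58 in PCB 77 and 5112, 400 and 148 in BaP. Of 108 log2 fold changes of named contigs, 108, 108 and 107 kept their call under total-count scaling, median-of-ratios scaling and a prior count of 0.5; contig 14033 in BaP, at 1.97, passed with 2.07 under the last. Of 90 list medians, the sign changed in 1 with a filter of 5 CPM, 6 as means and 3 with total-count scaling, and in 1 of 6 without the digestive profile. Simulated changes of 4-fold, at the threshold itself, passed in 38.0% to 58.0% of contigs, and depth set a floor of 0.248 to 0.273 CPM.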

Other observations

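The tests of explanations in this part, and the signatures behind its first 2 paragraphs, were chosen after the results were seen. Other contigs tied to the AHR and to conjugation also rose in all 3 treatments. The reading frame of contig 7350, among the highest contigs without a fixed signature, carries the basic region shared by the AHR and its repressor, which competes with the AHR for its DNA sites. Sulfotransferases attach sulfate to phenols and steroids, and of their motifs, the loop motif matched 4 contigs, of which 2 rose in TCDD, PCB 77 and BaP and 2 did neither, and the inner motif matched 1, which rose in all 3: contig 57153 by 153-fold (113 to 214), 115-fold (84.7 to 160.5) and 149-fold (109.7 to 208), contig 68174 by 107-fold, 66.4-fold and 37.1-fold, and contig 68175 by 43.8-fold, 62.05-fold and 129-fold. Both contigs with the leader of 5-aminolevulinate synthase 1, which starts heme synthesis, rose: contig 1026 by 7.59-fold, 6.96-fold and 12.9-fold and contig 17489 by 10.4-fold, 13.7-fold and 11.5-fold.

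Contigs with an albumin domain, from the main protein of plasma, numbered 5, with 2 chance matches among reversed proteins, and had median log2 fold changes of −0.73, −0.91 and −1.24 in TCDD, PCB 77 and BaP. They include contig 49313, and contig 733 fell 4.89-fold in TCDD and 9.29-fold in BaP; in PCB 77 its log2 fold change was −1.40, which did not pass. The CYP1A-type contig 8635 had 6 relatives with at least 95% nucleotide identity over at least 200 bases to it or, for contig 12752, to its relative contig 4940, and the 7 together held 437 CPM in control and 7104, 8179 and 7601 CPM in TCDD, PCB 77 and BaP, which was 16.3-fold (15.8 to 16.7), 18.7-fold (18.2 to 19.3) and 17.4-fold (16.9 to 17.9) over control. Of these, contig 4940 rose 75.2-fold, 91.7-fold and 153-fold, and contig 12752, with 98.6% identity to it, rose 13.0-fold, 18.5-fold and 12.6-fold. A more distant relative, contig 13515 (43.3% protein identity over 150 residues), had 200, 178, 95 and 248 counts in control, TCDD, PCB 77 and BaP.

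Fold changes correlated between treatments, and the 3 comparisons share 1 control. Counting error of the shared control library is argued against as the whole cause. Averaged over the simulations, it gave at most 4.76% of the observed covariance in any pair of treatments. Fish and tank differences of the control pool may add to the correlation and cannot be told apart from a shared response, because there was 1 control pool. To give the covariance alone, the control pool would need a biological coefficient of variation of at least 0.452, computed from the data.

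Near-identical contigs were often called separately: of the contigs that passed, 41.2% in TCDD, 44.1% in PCB 77 and 40.1% in BaP had a near-identical partner, against 27.8% of all contigs. Of the 554 calls of such contigs 401 (72.4%) were lost when near-identical contigs were summed, which decides nothing, since summing also dilutes a copy that truly changed. Reads divided between near-identical contigs in proportions that differ between libraries are argued against as the sole source of most calls: the partners' summed CPM changed the opposite way by at least 50% of the contig's change in 78 calls (14.1%) and the same way by at least 50% in 297 (53.6%). A fixed share of the reads of 1 copy counted on the other is argued against only in the CYP1A-type pair of contigs 12754 and 8635. There contig 12754 held 1.44% (Wilson interval 1.08 to 1.92) of the reads of both in control and at least 7.59% in the treated libraries. The CYP1A-type contigs 12800, 68504 and 68507 went the other way. Each held between 30.5% and 35.3% of their joint reads in every library, so a fixed division stays open there. A division on top of a change in the sum stays open, and gene copies or alleles that differ between the fish of the pools cannot be told apart from treatment with 1 pool per treatment, as where contig 4940 held 10.1% of the reads of contigs 4940 and 12752 in control and 57.8% in BaP.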
